A study of Mus musculus with 12 samples.

How the data were processed

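RNA was measured in 12 libraries from the cerebral cortex of C57BL/6 mice, 3 at each of E11, E13, E17 and P1. Per the labels, each library came from 1 µg of total RNA of the cortex of 1 animal, was made with the TruSeq Stranded mRNA kit, and was sequenced as 75 bp single reads on an Illumina NextSeq with all 12 libraries multiplexed. The authors' notes name bcl2fastq 2.18, STAR 2.5.2b, SAMtools, HTSeq 0.5.3 and DESeq2 1.8.1. The role of each tool, the genome build, the annotation release and the strand setting are not given in the sources used here, so no genome positions are given. The deposited values are raw read counts, with no normalization, for 50600 Ensembl gene identifiers per library, of which 50376 have a symbol. The 224 identifiers without a symbol took 0.067 to 0.088% of the counts, and 68 symbols belong to more than 1 identifier. Total counts were 28173745 to 45858712 per library, and the 10 most abundant genes of a library took 3.12 to 4.38% of its counts. In 12 pairs of libraries of the same age, counts differed far more than repeated sequencing of 1 library would give (chi-squared per degree of freedom 10.39 to 29.98), so no library was a copy of another.

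The groups were the 4 ages of the labels. E13 was compared with E11, E17 with E13, P1 with E17 and P1 with E11, each as the later age minus the earlier, and a test across all 4 ages was also made. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with age as the group and a minimum count of 10, which left 17847 genes and removed 32753, libraries were scaled with TMM factors (0.92 to 1.09), and a robust quasi-likelihood model with 1 coefficient per age was fitted to all 12 libraries. The common biological coefficient of variation was 0.106. Adjusted p-values are by Benjamini and Hochberg over all tested genes, two-sided, with a threshold of 0.05, and errors of fold changes are standard errors of the fitted log2 values. With 3 libraries per age these tests rest on a spread shared between genes and ages. Levels are CPM (counts per 1e6 counts of the TMM-scaled library), given as mean and SD over libraries. Bounds for genes without counts use a floor of 3 counts over the libraries of an age and, like intervals of ratios, cover counting error only.

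Before the data were examined, 37 gene lists with 407 genes were fixed, covering zinc genes, other metals and calcium, cell types of the cortex, cells of neighbouring tissues, and general processes such as the cell cycle and glycolysis. Of these, 36 lists with 3 or more tested members were tested for a shift against all other genes with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a comparison. The same test was also run with a correlation estimated from the data. Counts of changed genes in a list are over all genes tested; adjusted over the list alone, they differed by at most 1 gene, in 6, 3, 5 and 3 lists of the comparisons E13 with E11, E17 with E13, P1 with E17 and P1 with E11. The genes to be named were also fixed beforehand by a rule: every measured zinc gene, from each list the 2 largest rises and 2 largest falls past the threshold with a mean of at least 1 CPM at 1 of the ages compared, and over all genes the 5 largest rises and falls with at least 10 CPM and no overlap between the ages, leaving out sex-linked genes and unnamed transcripts. Genes under this rule whose call or size depended on 1 library are named only with the values without it, or not at all, and the results of some genes were left out because they are withheld for evaluation.

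The pipeline was tested on simulated data made from the fitted spread, with 100 genes changed 2-fold and 100 changed 1.5-fold in each comparison. Between 2 ages edgeR recovered 71 to 75% of the first and 43 to 53% of the second, and unchanged genes made up 4.2 to 8.4% of its calls. In its test across the 4 ages these were 69 to 74%, 42 to 53% and 3.2 to 9.3%. In the same simulation unchanged genes made up 15.9 to 20.2% of the calls of DESeq2 1.42.0 between 2 ages and 28.2 to 33% across the 4 ages, and for limma-voom 2.6 to 6.8% and 3.9 to 5.4%. The simulation changed few of the 17847 genes and drew each gene independently. In the real comparisons of 2 ages 40.1 to 82.3% of the tested genes changed, so these shares need not carry over to the data. As a check of the animals, Xist lay above 100 CPM in 5 libraries (1, 2, 1 and 1 at the 4 ages) and under 5 CPM in 7. The highest level of a Y-linked gene where Xist was high was 0.0956 CPM, and the lowest where it was low 11.9 CPM. Sex was not used in the model.

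Alternatives fixed beforehand were RLE factors, upper-quartile factors, scaling by library size alone, no filter on low counts, a filter at 1 CPM in 3 libraries, the erythroid genes removed, only the libraries of the ages compared, replicate letter as a block, DESeq2, limma-voom, and each library left out in turn. Leaving out E11 C, E13 C and E17 A together, the libraries of their ages with the most ventral or striatal marker counts, was added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9 from tables made with pandas 2.3.3 and numpy 2.4.6. Reads, isoforms and protein or zinc measurements were not analysed here.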

Results

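Gene expression was measured in the cerebral cortex of C57BL/6 mice at embryonic days E11, E13 and E17 and on postnatal day P1, by sequencing of poly(A)+ RNA. There were 3 libraries per age (A, B and C), each from the cortex of 1 embryo or pup, and the 3 animals of an age came from 3 different litters. The series title names zinc uptake and storage as its subject. The total read count was 31537145, 31093172 and 28720133 in the E11 libraries A, B and C and 35276008, 33581400 and 30767486 in the E13 libraries. It was 28173745, 29845843 and 45858712 at E17 and 40473592, 41616842 and 45555438 at P1. The first principal component of log2 CPM, counts scaled to a common library size, carried 83.4% of the variance and the second 6.5%. Across genes, which are not independent replicates, Pearson's r was 0.987 to 0.994 between libraries of the same age, 0.893 to 0.915 between E13 and E17, and 0.79 to 0.811 between E11 and P1.

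Of 17847 genes with enough counts to test, 16103 (90.2%) differed between the 4 ages in edgeR at an adjusted p of 0.05. Among the 29 genes on the zinc lists fixed beforehand (ZIP importers, which bring zinc into the cytosol; ZnT exporters, which remove it; metallothioneins, which bind it; and the zinc-sensing transcription factor Mtf1), 24 were tested and 20 changed across the ages (22 with upper-quartile factors and 23 with scaling by library size alone). The 4 without a change past the threshold were Slc39a9 (adjusted p = 0.759), Slc39a14 (adjusted p = 0.296), Slc30a1 (adjusted p = 0.168) and Mtf1 (adjusted p = 0.173), whose mean level was 28.2, 28.8, 31.2 and 29.4 CPM from E11 to P1. Slc39a4, Slc39a5, Slc30a2, Slc30a8 and Mt4 had 53, 21, 7, 4 and 2 counts over all 12 libraries and were too low to test. The summed level of the measured ZIP genes was 694, 647, 714 and 671 CPM at E11, E13, E17 and P1, that of the ZnT genes 292, 378, 339 and 354 CPM, and that of the metallothioneins 37.6, 65.9, 59.1 and 66.9 CPM. Slc30a10 alone made up 29.6, 118, 31.9 and 28.5 CPM of the ZnT sum, so the higher ZnT sum at E13 than at E11 came from this gene and not from the family. The lists of ZIP genes, ZnT genes and metallothioneins did not shift in any of the 4 comparisons in limma's camera test, and Mtf1, alone on its list, was not tested as a list.

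**Figure D1:**
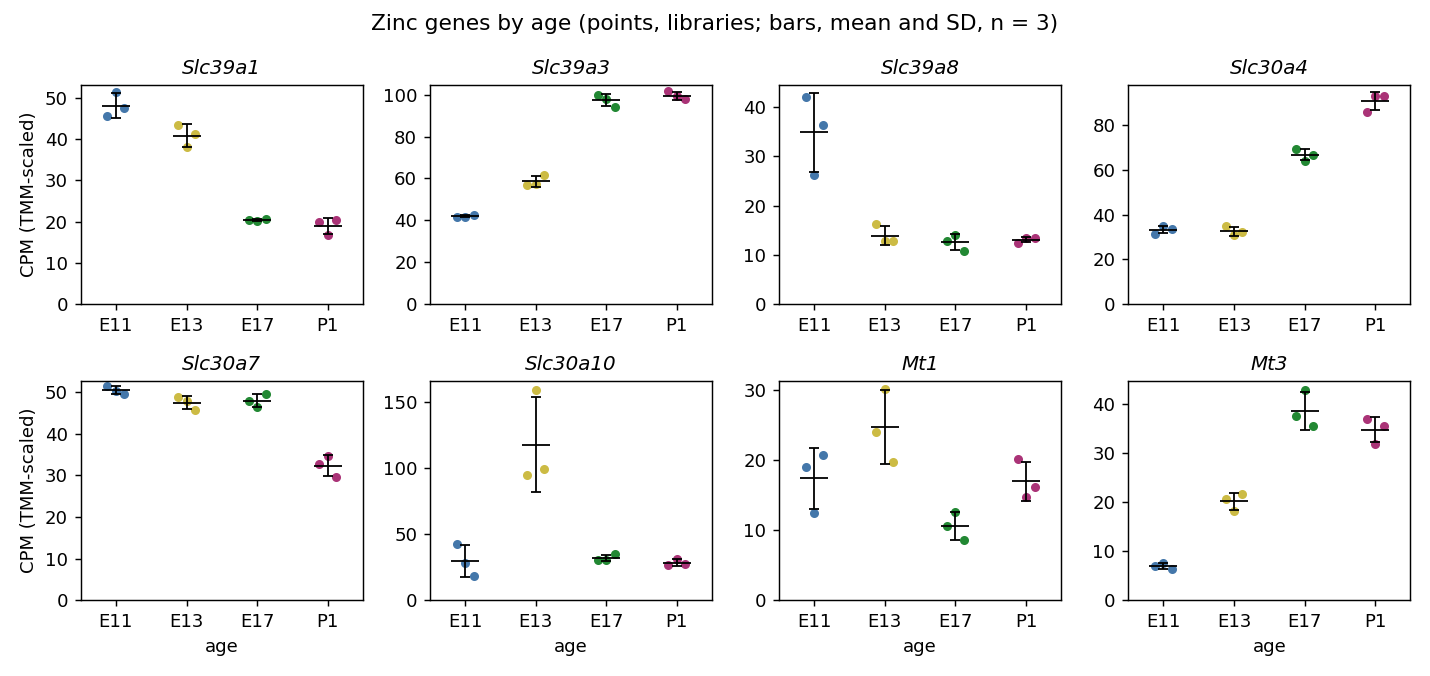
CPM of 8 zinc genes in each library at the 4 ages; points are libraries and bars are the mean and SD of 3 libraries. Slc30a10 stood at 118 CPM at E13 against 29.6 CPM at E11 and 31.9 CPM at E17, while Mt3 went from 6.94 CPM at E11 to 38.6 CPM at E17.

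The first comparison asks how the cortex at E13, when cortical neurons are being made, differs from the cortex at E11. Among zinc genes, Slc30a10 (ZnT10, ENSMUSG00000026614), a surface transporter best known for manganese export, rose from 29.6 ± 12 to 118 ± 35.7 CPM (SD, n = 3 each), a log2 fold change of 1.99 ± 0.28 (SE; adjusted p = 0.000391). Mt3 (ENSMUSG00000031760), the metallothionein characteristic of brain, rose from 6.94 ± 0.595 to 20.2 ± 1.73 CPM (SD, n = 3 each; log2 fold change 1.54, adjusted p = 2.26e-07). Slc39a8 (ZIP8, ENSMUSG00000053897), an importer of zinc and other divalent metals, fell from 34.9 ± 7.98 to 13.9 ± 1.98 CPM (SD, n = 3 each; log2 fold change -1.33, adjusted p = 3.73e-05). For these 3 genes, each E13 library lay on the same side of every E11 library. Slc39a3, a surface importer, rose by 0.48 on the log2 scale (adjusted p = 5.54e-06), Slc39a11 rose by 0.32 (adjusted p = 0.0017), and the log2 fold change of Slc39a10 was -0.31 (adjusted p = 0.01). In all, 10 of the 24 measured zinc genes changed, 6 up and 4 down, and 10 changed when adjusted over the list alone. The share of changed genes over all tested genes was 40.1%. The E11 libraries A, B and C held 42.04, 26.29 and 36.47 CPM of Slc39a8 and 16500, 5740 and 9680 CPM of the erythroid marker list, against 1270, 782 and 1760 CPM of that list at E13. The other 4 zinc calls each missed the threshold in at least 1 run with a library left out: Slc39a1 (log2 fold change -0.24, adjusted p = 0.0308), Slc39a12 (-1.22, adjusted p = 0.0385), Slc30a9 (0.15, adjusted p = 0.0182) and Mt2 (0.67, adjusted p = 0.0316). In these runs the log2 fold change stayed between -0.28 and -0.18 for Slc39a1 and between 0.13 and 0.17 for Slc30a9. Without E11 B their adjusted p was 0.131, 0.143, 0.0759 and 0.111, and 6 zinc genes changed. Without E13 B it was 0.124 for Slc39a1, 0.127 for Slc39a12 and 0.134 for Mt2, whose log2 fold change was then 0.35. Without E11 C it was 0.0568 for Slc39a1 and 0.0657 for Slc39a12, and without E13 C 0.0648 and 0.122. Without E11 A it was 0.0515 for Slc30a9 and 0.0636 for Mt2, and without E13 A the log2 fold change of Slc39a12 was -1.84. With no low-count filter the adjusted p was 0.0567 for Slc39a12, 0.0764 for Slc30a9 and 0.115 for Mt2, and with only the libraries of these ages it was 0.0509 for Slc39a12 and 0.0983 for Mt2. For Slc30a9 it was 0.0533 with scaling by library size alone and 0.0902 with upper-quartile factors. Without E11 C, E13 C and E17 A together, an alternative chosen after seeing the data, it was 0.124 for Slc39a1, 0.192 for Slc39a12 and 0.064 for Slc30a9.

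Neuronal genes rose from E11 to E13. All 10 pan-neuronal genes rose, with a median log2 fold change of 1.28, among them the neuronal differentiation factors Neurod6 (3.19 ± 0.24 SE, from 42 to 384 CPM) and Neurod2 (2.61). This list shifted in camera (adjusted p = 2.26e-07; adjusted p = 0.239 with an estimated correlation). Of 20 synapse genes 18 rose and 1 fell (camera adjusted p = 1.06e-09, adjusted p = 0.428 with an estimated correlation). Camk2b, a calcium-dependent kinase of synapses, rose by 4.57 on the log2 scale and the synaptic vesicle gene Syn2 by 3.16, while Camk2a had a log2 fold change of -0.96. Of 15 ionotropic glutamate receptor genes 11 rose and 1 fell (camera adjusted p = 4e-04, adjusted p = 0.428 with an estimated correlation), including Grin2b (4.41) and Gria1 (2.97). Of 16 genes of voltage-gated calcium channels, 12 rose and 1 fell (14 changed when adjusted over the list alone; camera adjusted p = 6.84e-05, and 0.428 as the adjusted p with an estimated correlation), including Cacna1i (2.78) and Cacna1e (1.96). Of 15 calcium pumps and exchangers 7 rose, such as Atp2b3 (2.64) and Slc8a3 (1.97), and 1 fell (camera adjusted p = 0.0316, adjusted p = 0.447 with an estimated correlation). Tiam2, a Rac activator, rose by 4.54, and Nos1, the neuronal nitric oxide synthase, by 4.37.

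Markers of intermediate progenitors, the dividing cells that give rise to cortical neurons, also rose: 7 of 8 passed (8 adjusted over the list alone), none fell, and the median log2 fold change was 1.03 (camera adjusted p = 0.00377, adjusted p = 0.447 with an estimated correlation). Sstr2 (2.16) and Insm1 (1.62) had the largest rises. Of 9 upper-layer neuron genes 7 rose, such as Unc5d (3.41) and Pou3f1 (1.5; camera adjusted p = 0.00174, adjusted p = 0.428 with an estimated correlation). Of 8 deep-layer genes 4 rose, such as Bcl11b (1.61) and Sox5 (1.47), and 1 fell, Tle4 (-0.45; camera adjusted p = 0.313). Of 8 genes of Cajal-Retzius cells 1 rose, their secreted signal Reln (1.59), and 1 fell, Lhx5 (-0.98, and -0.58 without E11 C), and the list did not shift (median -0.1, camera adjusted p = 0.654). Of 8 early neuroepithelium genes 6 fell (camera adjusted p = 0.00174, adjusted p = 0.428 with an estimated correlation), among them Hmga2, a chromatin protein of early stem cells, which went from 503 ± 163 to 62.6 ± 27.1 CPM (SD, n = 3 each; log2 fold change -3.01, adjusted p = 0.000133). Of 20 cell cycle genes 9 fell and none rose, with a median of -0.28 (camera adjusted p = 0.00121, adjusted p = 0.539 with an estimated correlation). Of 16 glycolysis genes 11 fell, such as Ldha (-0.6) and Pgk1 (-0.57), and 3 rose, including Eno2 (0.87) and Pfkp (0.78; 15 changed when adjusted over the list alone; camera adjusted p = 0.00616, adjusted p = 0.447 with an estimated correlation).

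Red cell genes were much lower at E13 than at E11. Of 10 erythroid genes 9 fell, with a median log2 fold change of -2.94 (camera adjusted p = 0.000358, adjusted p = 0.447 with an estimated correlation), including the embryonic globin Hbb-bh1 (-6.28) and the red cell anion exchanger Slc4a1 (-4.41). The erythroid mitochondrial iron importer Slc25a37 had a log2 fold change of -2.41, while the transferrin receptor Tfrc had one of -0.54. Of 12 genes of GABAergic interneurons and ventral telencephalon 3 rose, among them Lhx6 (1.59; camera adjusted p = 0.0246, adjusted p = 0.48 with an estimated correlation). Without E11 B the camera adjusted p of that list was 0.0891 and without E13 C it was 0.0708. The summed level of that list was 58.3, 50.3 and 98.9 CPM in E11 A, B and C and 77.6, 82.3 and 127 CPM in E13 A, B and C. In this comparison 7155 genes changed (4038 up, 3117 down), 1742 of them at least 2-fold, and 12 of 36 lists shifted (8 up, 4 down). The share of rises among changed genes depended on the scaling: it was 56.4%, and 50.2% with library size alone and 47.3% with upper-quartile factors. In camera with an estimated correlation 0 lists shifted, and 1 list had an unadjusted p under 0.05. Other splits of the same 6 libraries, which keep part of the age difference, shifted up to 10 lists.

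**Figure D2:**
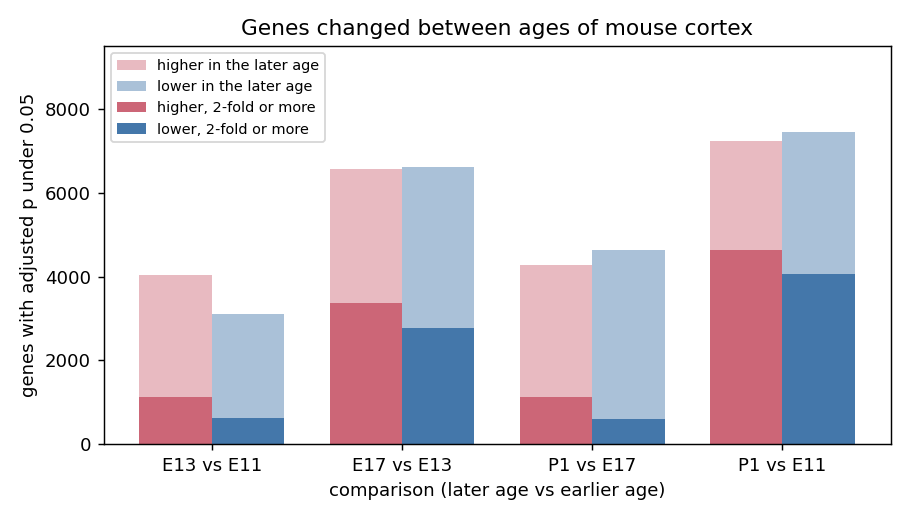
Number of genes higher and lower at the later age in each comparison (edgeR, adjusted p of 0.05, 3 libraries per age). From E13 to E17 6564 genes were higher and 6610 lower, and from E11 to E13 4038 were higher and 3117 lower, a split that turned with upper-quartile factors (3493 and 3890) for E11 to E13 and with RLE factors (6699 and 6408) for E13 to E17.

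The comparison of E17 with E13 spans 4 days in which most cortical neurons are made. Slc30a10 fell back from 118 to 31.9 ± 2.55 CPM (SD, n = 3; log2 fold change -1.88 ± 0.28 SE, adjusted p = 0.000145). Slc30a4 (ZnT4, ENSMUSG00000005802), an exporter of intracellular vesicles, rose from 32.6 to 66.7 CPM (log2 fold change 1.03 ± 0.06 SE, adjusted p = 3.2e-09). Slc39a1 (ENSMUSG00000052310), a surface importer, fell from 40.8 to 20.4 CPM (log2 fold change -1 ± 0.08 SE, adjusted p = 8.74e-08), while Slc39a3 rose from 58.6 to 97.3 CPM (0.73 ± 0.05 SE, adjusted p = 6.96e-09). The metallothioneins moved apart: Mt3 rose by 0.94 (adjusted p = 7.85e-07), whereas the broadly expressed Mt1 and Mt2 had log2 fold changes of -1.23 (from 24.7 to 10.6 CPM, adjusted p = 0.000282) and -1.1 (from 21 to 9.88 CPM, adjusted p = 0.000896). In all, 15 of 24 zinc genes changed, 9 up and 6 down, and 15 changed when adjusted over the list alone. The share of changed genes over all tested genes was 73.8%. Slc30a3 (ZnT3), which loads zinc into synaptic vesicles, rose from 0.18 to 0.767 CPM (2.1 ± 0.64 SE, adjusted p = 0.0107). The smaller changes were those of Slc39a6 (0.39), Slc39a13 (0.49), Slc30a9 (0.3), Slc39a7 (-0.18) and Slc30a5 (-0.22), with Slc39a11 (0.3) and Slc39a2 (0.98) also rising. The call of Slc39a11 was lost with scaling by library size alone (adjusted p = 0.121), and that of Slc39a2 without E11 C, E13 C and E17 A (adjusted p = 0.052), an alternative chosen after seeing the data. With scaling by library size alone, 3 genes that had not passed were called lower: Slc30a7 (-0.17, adjusted p = 0.0246), Slc39a9 (-0.2, adjusted p = 0.00172) and Slc30a6 (-0.36, adjusted p = 0.0112), the last also without E13 B (adjusted p = 0.0116). Over the same step the summed level of meningeal fibroblast markers went from 885, 802 and 1100 CPM in E13 A, B and C to 14.1, 16.4 and 14.4 CPM in the E17 libraries, and that of choroid plexus markers from 389, 346 and 43.4 to 3.86, 9.09 and 1.03 CPM.

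Genes of dividing cells fell from E13 to E17, and genes of neurons rose. All 20 cell cycle genes fell, with a median log2 fold change of -2.59 (camera adjusted p = 3.46e-09, adjusted p = 0.415 with an estimated correlation), including the mitotic genes Bub1 (-2.93) and Cdc20 (-2.85). Of 14 radial glia genes, which mark the stem cells of the cortex, 11 fell and 2 rose (camera adjusted p = 0.000489, adjusted p = 0.415 with an estimated correlation). Among them Hes1, a Notch target, had a log2 fold change of -3.27 and Emx2 of -2.7, while the glutamate transporter Slc1a3 rose by 1.01 and Fabp7 by 0.66. Of 8 intermediate progenitor genes 7 fell, including Neurog2 (-2.79; camera adjusted p = 0.0133, adjusted p = 0.435 with an estimated correlation). All 10 pan-neuronal genes rose, such as Nefl (3.77) and Stmn2 (2.99; camera adjusted p = 2e-04, adjusted p = 0.415 with an estimated correlation). Of 20 synapse genes 18 rose and 1 fell (camera adjusted p = 1.5e-06, adjusted p = 0.415 with an estimated correlation), with Camk2b at 4.22, the vesicle calcium sensor Syt1 at 3.43 and the vesicular glutamate transporter Slc17a6 at -0.41. Of 15 ionotropic glutamate receptor genes 14 rose and none fell (camera adjusted p = 5.35e-05, adjusted p = 0.415 with an estimated correlation), including Grin3a (6.46) and Grin2b, which went from 29 ± 6.43 to 695 ± 49.3 CPM (SD, n = 3 each; 4.58 ± 0.15 SE).

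Of 9 upper-layer genes 8 rose (camera adjusted p = 0.00707, adjusted p = 0.415 with an estimated correlation), among them Pou3f1, which went from 6.19 to 63.2 CPM (3.35 ± 0.14 SE). Of 8 deep-layer genes 7 rose and 1 fell, such as Ldb2 (3.22) and Fezf2 (-0.49), and the list did not shift (camera adjusted p = 0.0801). All 9 oligodendrocyte lineage genes rose (camera adjusted p = 0.0105, adjusted p = 0.415 with an estimated correlation). The astrocyte list did not shift (7 of 10 rose and 2 fell, camera adjusted p = 0.221), with the gap junction gene Gja1 at -3.14, nor did that of microglia (4 of 11 rose and 1 fell, 4 changed when adjusted over the list alone, camera adjusted p = 0.417). Of 12 genes of GABAergic interneurons and ventral telencephalon 11 rose, including Npy (7.11) and Lhx6 (3.83; camera adjusted p = 0.0213, adjusted p = 0.435 with an estimated correlation). Of 8 striatal genes 7 rose (8 adjusted over the list alone; camera adjusted p = 0.0167, adjusted p = 0.435 with an estimated correlation), and their summed level was 112, 66.2 and 84 CPM in E17 A, B and C. Of 16 calcium channel genes 13 rose, such as Cacna1d (3.21), and 2 fell (camera adjusted p = 0.00166, adjusted p = 0.435 with an estimated correlation). Of 15 calcium pumps and exchangers 13 rose, such as Slc8a1 (3.18) and Slc24a3 (2.86), and 1 fell (camera adjusted p = 0.00166, adjusted p = 0.415 with an estimated correlation).

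Meningeal and choroid plexus genes were far lower at E17. All 8 meningeal fibroblast genes fell, with a median log2 fold change of -6.21 (camera adjusted p = 0.00166, adjusted p = 0.435 with an estimated correlation), including the collagen Col1a1, from 171 ± 38.6 to 1.18 ± 0.245 CPM (SD, n = 3 each). Of 7 choroid plexus genes 6 fell, such as Clic6 (-6.41; camera adjusted p = 0.0215, adjusted p = 0.435 with an estimated correlation), and with scaling by library size alone the camera adjusted p of that list was 0.0618. Of 10 erythroid genes 5 fell, with a median of -1.34, and the embryonic globin Hbb-y went from 759 ± 345 to 0.0811 ± 0.0404 CPM (SD, n = 3 each). The erythroid list passed camera (adjusted p = 0.0398; adjusted p = 0.544 with an estimated correlation), but not without E13 C (adjusted p = 0.0598) or E17 B (adjusted p = 0.0688). It also missed with upper-quartile factors (0.0649), library size alone (0.0991), a filter at 1 CPM in 3 libraries (0.0542) and without E11 C, E13 C and E17 A (0.0576). The lists of surface ectoderm (3 of 4 fell, camera adjusted p = 0.192) and of muscle and cartilage (2 of 4 rose and 1 fell, median 1.19, camera adjusted p = 0.609) did not shift. In the latter, the muscle actin Acta1 rose by 2.76 and the cartilage collagen Col2a1 had a log2 fold change of -3.73. Of 10 endothelial genes 3 rose and 6 fell (camera adjusted p = 0.382), with Cldn5 at 0.94 and Cdh5 at -1.39. In this comparison 13174 genes changed (6564 up, 6610 down), 6129 of them at least 2-fold, and 16 of 36 lists shifted (10 up, 6 down). In camera with an estimated correlation 0 lists shifted, and 4 lists had an unadjusted p under 0.05. Other splits of the same 6 libraries, which keep part of the age difference, shifted up to 16 lists. With scaling by library size alone the median of all genes moved by -0.18, and 39.8% of the changed genes were higher at E17 in place of 49.8%, against 51.1% with RLE factors.

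**Figure D3:**
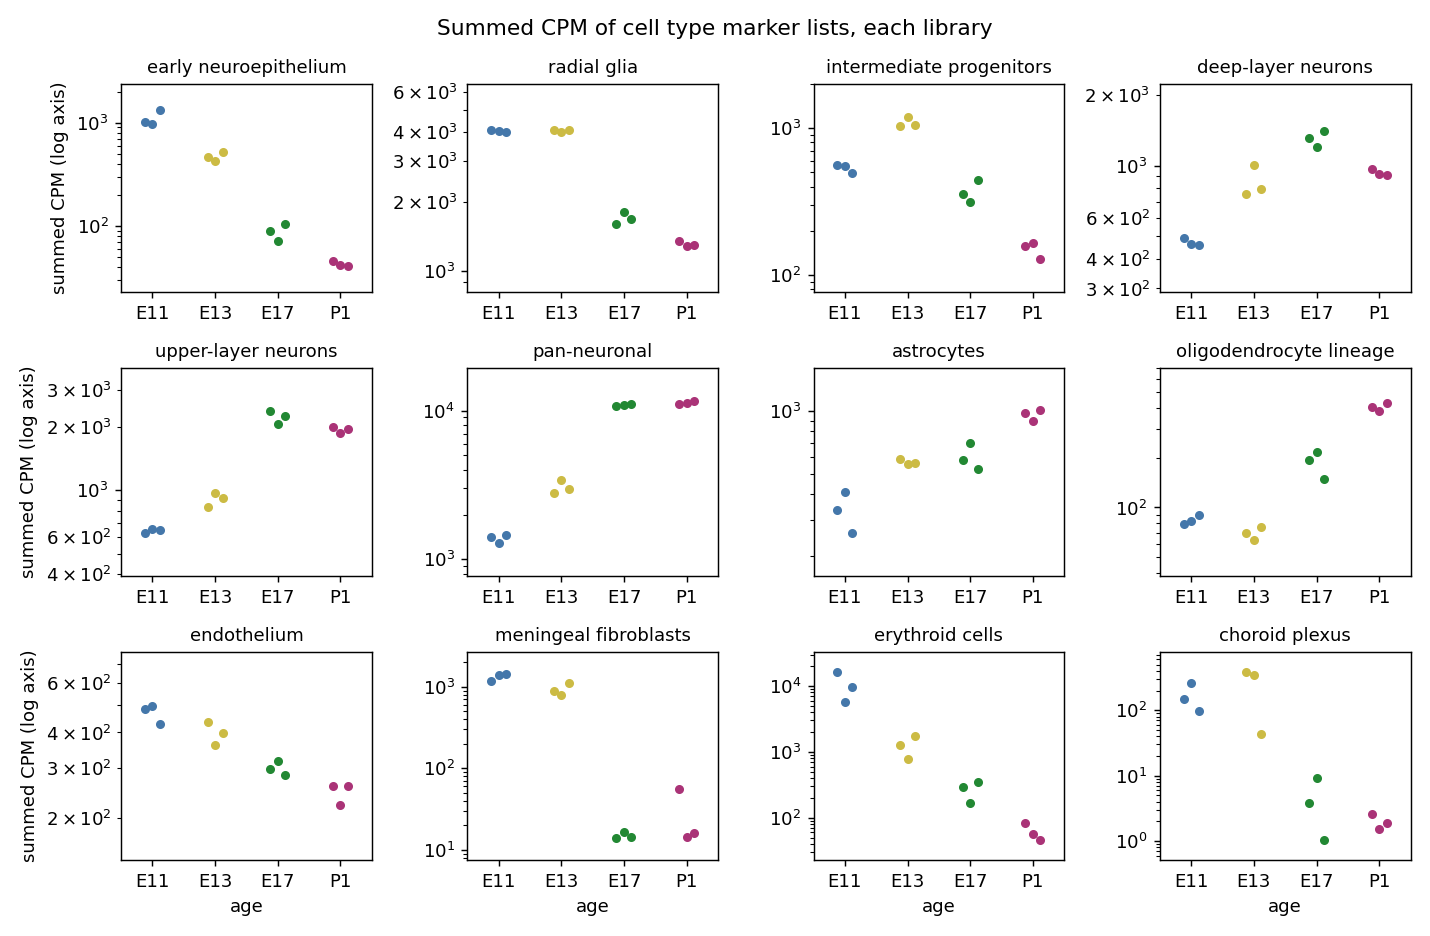
Summed CPM of 12 lists of cell type markers in each library (log axis). The meningeal sum lay between 802 and 1100 CPM in the E13 libraries and between 14.1 and 16.4 CPM in the E17 libraries.

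The comparison of P1 with E17 covers birth. Among zinc genes, Slc30a7 (ZnT7, ENSMUSG00000054414), an exporter of the early secretory pathway, fell from 47.9 to 32.3 CPM (log2 fold change -0.57 ± 0.06 SE, n = 3 each, adjusted p = 1.03e-05 in edgeR). Slc30a4 rose from 66.7 to 90.7 CPM (0.44 ± 0.06 SE, adjusted p = 5.33e-05), and each P1 library lay above every E17 library. Slc30a3 rose from 0.767 to 2.58 CPM (1.72 ± 0.47 SE, adjusted p = 0.0086). Slc39a6 had a log2 fold change of -0.24 (adjusted p = 0.000535) and Slc30a9, the mitochondrial member of the family, of 0.17 (adjusted p = 0.00714). In all, 10 of 24 zinc genes changed, 5 up and 5 down, and 10 changed when adjusted over the list alone. The share of changed genes over all tested genes was 49.9%. The other 5 zinc calls each missed the threshold in at least 1 run with a library left out: Mt1 (0.69, adjusted p = 0.0208), Mt2 (0.62, adjusted p = 0.0387), Slc39a10 (-0.22, adjusted p = 0.0412), Slc39a11 (-0.23, adjusted p = 0.00937) and Slc30a5 (-0.17, adjusted p = 0.0136). Without P1 A their adjusted p was 0.07, 0.109, 0.0557, 0.0585 and 0.0563 in that order, and 5 zinc genes changed. Without E17 C it was 0.0908 for Mt1, 0.134 for Mt2 and 0.0577 for Slc30a5, and without E17 A 0.0785 for Mt2, 0.133 for Slc39a10 and 0.0724 for Slc30a5. Without E17 B it was 0.0509 for Mt2 and 0.122 for Slc39a10, without P1 B 0.0579 and 0.229, and without P1 C 0.0515 for Mt2, 0.0782 for Slc39a10 and 0.0904 for Slc30a5. With no low-count filter it was 0.0757 for Mt1, 0.122 for Mt2 and 0.0638 for Slc30a5. For Slc39a10 it was 0.0617 with RLE factors, 0.0643 with upper-quartile factors, 0.0554 with a filter at 1 CPM in 3 libraries and 0.061 in DESeq2. Without E11 C, E13 C and E17 A together it was 0.0933 for Slc39a10 and 0.0771 for Slc30a5. The meningeal marker sum was 56.1 CPM in P1 A against 14.2 and 16 CPM in P1 B and C, and Mt1 stood at 20.11, 14.67 and 16.16 CPM in these libraries.

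Progenitor genes fell further after E17. All 20 cell cycle genes fell, with a median log2 fold change of -1.29 (camera adjusted p = 4.35e-11, adjusted p = 0.512 with an estimated correlation), among them Mki67 (-1.59) and Bub1 (-1.58). Of 8 intermediate progenitor genes 7 fell (camera adjusted p = 0.00151, adjusted p = 0.512 with an estimated correlation), among them Neurog2, from 35.9 ± 9.47 to 2.69 ± 1.25 CPM, and Eomes, from 91.6 ± 24 to 12 ± 5.34 CPM (SD, n = 3 each). Of 14 radial glia genes 8 fell and 1 rose (camera adjusted p = 0.0213, adjusted p = 0.512 with an estimated correlation), with Vim at -1.21, Pax6 at -1 and Slc1a3 at 0.44. Of 8 early neuroepithelium genes 5 fell, such as Igf2bp1 (-1.25; camera adjusted p = 0.0312, adjusted p = 0.593 with an estimated correlation). Of 20 synapse genes 15 rose and 1 fell (camera adjusted p = 0.000675, adjusted p = 0.611 with an estimated correlation), with Stx1a at 1.26, Camk2a at 1.14 and Slc17a6 at -0.53. Nrgn, a calmodulin-binding protein of dendrites, rose from 30.3 ± 8.51 to 254 ± 78 CPM (SD, n = 3 each; 3.07 ± 0.23 SE). Of 15 ionotropic glutamate receptor genes 5 rose, such as Grin1 (1.21) and Grin2d (1.06), and the list did not shift (camera adjusted p = 0.204). Pan-neuronal genes (4 of 10 rose and 1 fell, camera adjusted p = 0.329) and upper-layer genes (1 of 9 rose and 3 fell, camera adjusted p = 0.628) did not shift as lists either.

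Astrocyte and oligodendrocyte lineage genes rose toward P1. Of 10 astrocyte genes 6 rose and none fell (camera adjusted p = 0.0278, adjusted p = 0.512 with an estimated correlation), among them the water channel Aqp4 (2.36, from 6.01 to 30.4 CPM). Of 9 oligodendrocyte lineage genes 8 rose (camera adjusted p = 0.0278, adjusted p = 0.512 with an estimated correlation). Of 10 immediate early genes, which neuronal activity induces, 6 rose and 1 fell (camera adjusted p = 0.0312, adjusted p = 0.471 with an estimated correlation), with Egr1 at 2.69, Egr2 at 2.05 and Dusp1 at -0.83. Of 15 calcium pumps and exchangers 12 rose, such as Slc24a3 (1.71; camera adjusted p = 0.00151, adjusted p = 0.471 with an estimated correlation). Of 16 calcium channel genes 9 rose, such as Cacna1g (1.22; camera adjusted p = 0.0278, adjusted p = 0.616 with an estimated correlation), and of 19 TRP channel genes 11 rose and 3 fell, with Trpc5 at 1.63 and Trpc2 at -0.49 (camera adjusted p = 0.0278, adjusted p = 0.471 with an estimated correlation). Of 8 deep-layer genes 5 fell, such as Sox5 (-0.95) and Tbr1 (-0.64), and 1 rose, Ldb2 (0.39; camera adjusted p = 0.157). Of 18 iron and copper genes 5 rose and 3 fell (camera adjusted p = 0.329): the transferrin receptor Tfrc rose by 0.86 and the copper pump Atp7a had a log2 fold change of -1.19. In this comparison 8913 genes changed (4283 up, 4630 down), 1735 of them at least 2-fold, and 11 of 36 lists shifted (7 up, 4 down). The share of rises was 48.1%, and 51% with RLE and 52.4% with upper-quartile factors. In camera with an estimated correlation 0 lists shifted, and 3 lists had an unadjusted p under 0.05. Other splits of the same 6 libraries, which keep part of the age difference, shifted up to 11 lists.

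Over the whole span from E11 to P1, 16 of 24 zinc genes changed, 9 up and 7 down, and 16 changed when adjusted over the list alone. The share of changed genes over all tested genes was 82.3%. Mt3 rose to 34.8 ± 2.58 CPM (SD, n = 3; log2 fold change 2.32 ± 0.1 SE, adjusted p = 6e-11), Slc30a4 rose from 33.4 to 90.7 CPM (1.44 ± 0.06 SE, adjusted p = 4.45e-11) and Slc39a3 from 42 to 99.5 CPM (1.25 ± 0.05 SE, adjusted p = 1.5e-11). Slc39a8 went from 34.9 to 13.1 CPM (-1.42 ± 0.16 SE, adjusted p = 2.22e-06) and Slc39a1 from 48.1 to 19 CPM (-1.34 ± 0.08 SE, adjusted p = 2.02e-09). Slc30a3 rose from 0.136 to 2.58 CPM (4.26 ± 0.61 SE, adjusted p = 2.69e-05), and its log2 fold change was 6.29 without E11 C and 3.66 without E11 B. Slc39a2, at a low level, rose from 2.43 to 6.24 CPM (1.36 ± 0.26 SE, adjusted p = 0.000328). Smaller rises were those of Slc39a13 (0.71), Slc30a9 (0.62), Slc39a11 (0.39) and Slc39a6 (0.2). With scaling by library size alone, which moved the median of all genes by -0.23, the log2 fold change of Slc39a6 was -0.02 (adjusted p = 0.597). Smaller falls were those of Slc30a7 (-0.64), Slc30a6 (-0.54), Slc30a5 (-0.46), Slc39a10 (-0.38) and Slc39a7 (-0.24). Slc30a10 (-0.06 ± 0.28 SE, adjusted p = 0.857) and Mt1 (-0.03) did not pass between E11 and P1. Mtf1, Slc39a9, Slc39a14 and Slc30a1 did not pass either, but with scaling by library size alone they were called lower, with log2 fold changes of -0.17, -0.23, -0.44 and -0.4 (adjusted p = 0.023, 0.000452, 0.00171 and 0.00581). With upper-quartile factors Slc39a14 (adjusted p = 0.0177) and Slc30a1 (adjusted p = 0.0497) were called lower as well.

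Neuronal and oligodendrocyte lineage genes were higher at P1 than at E11. All 15 ionotropic glutamate receptor genes rose, with a median log2 fold change of 3.4 (camera adjusted p = 3.1e-05, adjusted p = 0.353 with an estimated correlation), and Grin2b went from 1.37 ± 0.239 to 771 ± 16 CPM (SD, n = 3 each; 9.14 ± 0.19 SE). Of 20 synapse genes 19 rose (camera adjusted p = 2.53e-07, adjusted p = 0.371 with an estimated correlation), such as Camk2b (9.46), and all 10 pan-neuronal genes rose (camera adjusted p = 9.13e-05, adjusted p = 0.353 with an estimated correlation), such as Gap43 (4.76). Of 9 upper-layer genes 8 rose and 1 fell (camera adjusted p = 0.00824, adjusted p = 0.371 with an estimated correlation), with Pou3f1 at 5.66. All 9 oligodendrocyte lineage genes rose (camera adjusted p = 0.00879, adjusted p = 0.371 with an estimated correlation), such as Lhfpl3 (6.41). The lists of astrocytes (7 of 10 rose and 2 fell, camera adjusted p = 0.0788) and microglia (7 of 11 rose and 1 fell, camera adjusted p = 0.308) did not shift. Of 12 GABAergic and ventral genes 9 rose, with Npy at 10.32 (camera adjusted p = 0.0112, adjusted p = 0.415 with an estimated correlation), and of 8 striatal genes 7 rose (camera adjusted p = 0.0336, adjusted p = 0.415 with an estimated correlation). Calcium channels had 14 rises and 1 fall among 16 genes (camera adjusted p = 0.000351, adjusted p = 0.371 with an estimated correlation), and calcium pumps and exchangers 13 and 1 among 15 (camera adjusted p = 0.000685, adjusted p = 0.353 with an estimated correlation).

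All 20 cell cycle genes fell between E11 and P1, with a median of -4.19 (camera adjusted p = 1.9e-08, adjusted p = 0.385 with an estimated correlation), as did all 8 early neuroepithelium genes (camera adjusted p = 0.00445, adjusted p = 0.371 with an estimated correlation), with Hmga2 at -10.93. Of 14 radial glia genes 12 fell and 2 rose (camera adjusted p = 0.00158, adjusted p = 0.353 with an estimated correlation), with Emx2 at -4.01 and Slc1a3 at 1.92. Of 10 erythroid genes 9 fell (10 adjusted over the list alone; camera adjusted p = 0.00242, adjusted p = 0.415 with an estimated correlation), and the summed level of that list at P1 was 83.9, 57.6 and 45.6 CPM. Of 8 meningeal genes 6 fell, such as Lum (-6.5; camera adjusted p = 0.0215, adjusted p = 0.479 with an estimated correlation), and the camera adjusted p was 0.0511 with scaling by library size alone. Rprml, which had no counts at E11, was at least 344-fold higher at P1, against a floor of 3 counts over the 3 E11 libraries. In this comparison 14693 genes changed (7235 up, 7458 down), 8681 of them at least 2-fold, and 14 of 36 lists shifted (9 up, 5 down). The share of rises was 49.2%, and 41.5% with library size alone, 45.7% with upper-quartile factors and 50.6% with RLE factors. In camera with an estimated correlation 0 lists shifted, and 4 lists had an unadjusted p under 0.05. Other splits of the same 6 libraries, which keep part of the age difference, shifted up to 16 lists.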

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

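The alternative without E11 C, E13 C and E17 A was chosen only after the results were seen; the other alternatives were planned, and none of the planned ones was left out. Over 462 named results and all alternatives there were 7842 values, of which 7570 kept direction and side of the threshold, 199 no longer passed and 23 newly passed. Signs changed in 53 values, of which 1 is among those that no longer passed and 2 among those that newly passed. Of 417 results that passed, 51 missed the threshold under at least 1 alternative. Of 308 values of the 18 counts, 302 lay within 1.5 times the reported count. With an estimated correlation in camera, 0, 0, 0 and 0 lists shifted in the comparisons E13 with E11, E17 with E13, P1 with E17 and P1 with E11. With the preset value these were 12, 16, 11 and 14. The estimated correlation was 0.79 for the cell cycle list, 0.5 for synapse and 0.02 for TRP channels, against the preset 0.01. Why lists with an estimate near the preset value also missed was not tested. Leaving out 1 library in turn gave 6 to 10 zinc genes from E11 to E13 (6 without E11 B) and 5 to 8 from E17 to P1 (5 without P1 A), with fewer samples in each. Without E11 C, E13 C and E17 A, 4823, 11916, 7627 and 14468 genes and 8, 14, 8 and 16 zinc genes changed. Zinc genes that newly passed, other than with scaling by library size alone or upper-quartile factors, were from E11 to E13 Mt1 (adjusted p = 0.0431 in DESeq2, 0.0468 in limma-voom, 0.0419 without E13 C, 0.0366 without E11 C, E13 C and E17 A) and Slc30a1 (0.0442 without E13 B). From E13 to E17 they were Slc39a12 (0.0333 in DESeq2, 0.00701 without E13 A, 0.0154 without E17 C), Slc39a10 (0.0418 without E13 C) and Slc30a6 (0.0116 without E13 B), and from E17 to P1 Slc30a6 (0.0347 with only these ages, and 0.0482 with library size alone). Slc39a7 from E11 to E13 passed with library size alone (0.0321) and upper-quartile factors (0.0173). Depth limits genes such as Slc30a3, at 0.136 CPM at E11.

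Signs changed as follows (log2 fold changes), all but Slc39a6 from E11 to P1 for results that had not passed, and the cause was not tested. With scaling by library size alone, which moved the median of all genes by -0.18 from E13 to E17 and by -0.23 from E11 to P1, they were -0.04 for Slc39a10, -0.17 for Slc30a7 and -0.07 for Mtf1 from E13 to E17, and -0.02 for Slc39a6, -0.03 for Mt2 and -0.17 for Mtf1 from E11 to P1. Of these, Slc30a7 (adjusted p = 0.0246) and Mtf1 from E11 to P1 (adjusted p = 0.023) passed the threshold in the new direction. Upper-quartile factors, which moved that median by -0.08 and -0.1, gave -0.02 for Mtf1 from E11 to E13, -0.07 for Slc30a7 from E13 to E17 and -0.04 for Mtf1 from E11 to P1. With no filter, Slc39a9, Slc39a14 and Slc30a1 from E13 to E17 were each 0.02, and Slc39a9 and Mt1 from E11 to P1 were 0.03 and 0.01. With RLE factors and with DESeq2 the same 3 genes from E13 to E17 were each 0.01 and Slc39a9 from E11 to P1 was 0.03. limma-voom gave 0.01 for Slc30a10 from E11 to P1, and the ages compared alone gave 0.02 for Slc39a9 from E11 to P1. Without E11 C, E13 C and E17 A, Slc30a7 from E13 to E17 was -0.01 and Mt1 from E11 to P1 was 0.11.

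Leaving out 1 library in turn, the cause again not tested, the values from E11 to E13 ranged from -0.07 to 0.54 for Slc39a2, -0.03 to 0.17 for Slc39a13, -0.15 to 2.47 for Slc30a3, -0.08 to 0.01 for Slc30a4 and -0.16 to 0.04 for Slc30a6. From E13 to E17 they ranged from -0.05 to 0.01 for Slc39a9, -0.1 to 0.1 for Slc39a14, -0.1 to 0.09 for Slc30a1 and -0.01 to 0.04 for Slc30a7. From E17 to P1 they ranged from -0.14 to 0.01 for Slc39a1, -0.15 to 0.23 for Slc39a2, -0.04 to 0.15 for Slc39a8 and -0.11 to 0.02 for Slc39a14. From E11 to P1 they ranged from -0.04 to 0.03 for Slc39a9, -0.31 to 0.29 for Slc30a10 and -0.23 to 0.1 for Mt1.

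The replicate letters do not pair the libraries, since the animals came from different litters. After the mean of each age was removed, r between libraries of the same letter ran from -0.34 to 0.33 over 18 pairs, with 4 over 0.1, and 6 pairs were highest with their own letter. With the letter as a block, 6756, 12975, 8542 and 14582 genes changed in the comparisons E13 with E11, E17 with E13, P1 with E17 and P1 with E11. With that block the adjusted p was 0.0507 for Slc39a12 from E11 to E13 and 0.0607 for Slc39a10 from E17 to P1, which no longer pass.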

Other observations

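In this part the tests of the fall of meningeal genes, of the peak of Slc30a10, of the fall and of the rise of Mt1 and Mt2, and of the splits between 2 ages were chosen only after the results were seen; the splits across all 4 ages were planned.

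Of 16 glycolysis genes 4 rose and 11 fell from E13 to E17, with a median of -0.79 (camera adjusted p = 0.0755). The hexokinase Hk1 rose from 54.3 ± 6.13 to 281 ± 16.4 CPM (SD, n = 3 each; log2 fold change 2.37 ± 0.09 SE) and the phosphofructokinase Pfkp from 19.4 to 145 CPM (2.9), while the hexokinase Hk2 went from 62.8 to 10.5 CPM (-2.57) and Tpi1 from 375 to 150 CPM (-1.32). Of 16 cholesterol synthesis genes 11 rose and 2 fell from E13 to E17 (camera adjusted p = 0.0236; adjusted p = 0.544 with an estimated correlation), with Hmgcs1 at 1.2, Mvd at 1.08 and Idi1 at -0.52. In the other steps more of them fell: 1 rose and 6 fell from E11 to E13 (camera adjusted p = 0.0763), and 1 rose and 5 fell from E17 to P1 (camera adjusted p = 0.391). Of 19 TRP channel genes 9 rose and 7 fell from E13 to E17 (camera adjusted p = 0.51), and of 5 genes of store-operated calcium entry 3 rose (camera adjusted p = 0.192). The receptor-operated channel gene Trpc4 rose from 0.96 ± 0.302 to 32.8 ± 7.21 CPM (SD, n = 3 each) and Orai2, of store-operated calcium entry, from 14.9 to 62.1 CPM. Of 9 hypoxia-responsive genes 1 rose and 2 fell from E11 to E13 (camera adjusted p = 0.654), and 5 rose and 2 fell from E13 to E17 (camera adjusted p = 0.42). From E17 to P1 1 of them rose and 5 fell (camera adjusted p = 0.204). Of 8 glucocorticoid-responsive genes 1 rose and 3 fell from E11 to E13 (camera adjusted p = 0.35). In that list 5 rose from E13 to E17 (camera adjusted p = 0.0755), and 4 rose and 3 fell from E17 to P1 (camera adjusted p = 0.635). Ndrg1, of the hypoxia list, rose from E11 to E13 (3.03) and from E13 to E17 (2.94). The glucocorticoid-responsive kinase Sgk1 fell from E11 to E13 (-0.81) and rose from E13 to E17 (2.2) and from E17 to P1 (0.94). Of 10 immediate early genes 4 rose and 3 fell from E13 to E17 (8 changed when adjusted over the list alone). Ier2 (-1.74) and Jun (-1.68) fell and Dusp1 (0.56) rose, and the list had a median of 0.3, a mean of 0.01 and a downward camera direction (adjusted p = 0.896).

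The median, the mean and the camera direction of a list differed in sign in 4 lists from E11 to E13, 1 from E13 to E17, 7 from E17 to P1 and 2 from E11 to P1, and none of these lists shifted. Among them were the ZnT exporters from E11 to E13 (median -0.05, mean 0.26, upward), from E17 to P1 (-0.04, 0.15, upward) and from E11 to P1 (-0.11, 0.56, upward), and the ZIP importers from E17 to P1 (0.04, 0, downward). From E11 to E13 they also included meningeal fibroblasts (-0.36, 0.4, downward). With the genes of at most 3 counts set to their bound, the median of the astrocyte list from E11 to E13 was 0.68 in place of 0.83 and that of the early neuroepithelium list from E13 to E17 was -1.51 in place of -1.74.

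The fall of the meningeal list from E13 to E17 kept a median of at most -6.19 under 4 scalings. These scalings differ too little to remove such a fall, since library size alone moved the median of all genes by -0.18. The choice among them therefore does not account for it. A dilution of all non-neural cells by growing numbers of neurons needs blood vessel genes to fall alike, and the lower of the endothelial and pericyte medians was -0.57. Less surrounding tissue taken along at the later ages would lower the other neighbouring lists. Choroid plexus had a median of -5.21, surface ectoderm of -3.04 and diencephalon and midbrain of -1.77. The striatal list went the other way, with a median of 2.45, as did that of GABAergic interneurons and ventral telencephalon, with 3.27. Muscle and cartilage had a median of 1.19 with members going both ways, while its sum went from 196, 210 and 191 CPM at E13 to 15.3, 19.2 and 19.8 CPM at E17. Age and dissection cannot be told apart, so this stays open, since the labels give no dissection that differs within an age, and a change of the tissue with age stays open and untested.

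For the peak of Slc30a10 at E13, more meninges or choroid plexus in the E13 libraries was examined. It would raise their markers by about the 1.99 that Slc30a10 rose. Their medians from E11 to E13 were -0.36 (SD of members 1.44) and -0.09 (SD 0.92). The meningeal list was split, however: of 8 genes 2 rose, both by more than Slc30a10, 1 fell, and the mean was 0.4. Its median thus argues against more meninges as a whole, but not against more of the cells that express these 2 genes. Of 7 choroid plexus genes none rose and 1 fell. A candidate explanation is the abundance of intermediate progenitors, whose median was 1.03 from E11 to E13 and -1.98 from E13 to E17. It was the only 1 of 36 lists with a median of at least 1 and then at most -1. These cuts asked less than the rise of about 1.99 asked of the meningeal and choroid plexus lists, so the tests were not alike. The progenitor sum was 565, 555 and 497 CPM at E11 and 355, 312 and 442 CPM at E17, while Slc30a10 stood at 29.6 and 31.9 CPM. From E17 to P1, however, that list had a median of -1.83 while Slc30a10 had a log2 fold change of -0.16. An effect of age in other cells was not tested.

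For the lower Mt1 and Mt2 at E17, less zinc read by Mtf1 was examined on the assumption that its target Slc30a1 moves by a comparable amount. The lower 95% bound of the Slc30a1 change was -0.29, above -0.55, a cut set from the smaller metallothionein fall after the results were seen. This argues only against a zinc change that moves these genes alike. Whether Slc30a1 responds as strongly as Mt1 and Mt2 was not tested, so less zinc stays open. A lower glucocorticoid signal would lower its responsive genes, of which 5 of 8 rose and none fell (median 0.73). That list did not shift, however (camera adjusted p = 0.0755), and its genes may change with age for other reasons, so this does not decide. Loss of meningeal tissue may contribute, as that list had a median of -6.21, and cannot be told apart from age because both differ between the same libraries. At the earlier ages Mt1 did not follow the meningeal sum. In E13 A, B and C the sum was 885, 802 and 1100 CPM and Mt1 24.05, 30.21 and 19.72 CPM. In E11 A, B and C the sum was 1180, 1390 and 1430 CPM and Mt1 19, 12.5 and 20.7 CPM. At P1, however, library A was the highest in both (56.1 and 20.11 CPM), so a part in the fall stays open. For the higher levels at P1, 2 of the 3 P1 libraries had Mt1 above every E17 library with a meningeal sum within the E17 range (highest 16.4 CPM), which argues against meningeal tissue as the whole source. An effect of age or birth was not tested.

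Splits of the 6 libraries of 2 ages into other groups of 3 number 10 with the real one, too few for a share under 0.05. The real split gave 7155, 13174, 8913 and 14693 changed genes in the comparisons E13 with E11, E17 with E13, P1 with E17 and P1 with E11, 1742, 6129, 1735 and 8681 genes changed at least 2-fold, and 10, 15, 10 and 16 zinc genes, and the highest of the other splits gave 0 for each. In each of these, 1 split was as large, the real one. For camera lists the real split gave 12, 16, 11 and 14 and the highest of the others 10, 16, 11 and 16, with 1, 3, 3 and 4 splits as large. Each other split holds the 2 ages in unequal numbers in its groups and so keeps part of the age difference. It cannot show how many lists would shift without one. Across all 4 ages, 1 of 100 splits, the real one, gave as many changed genes (16103, highest other 10922) and as many zinc genes (20, highest other 11), a share under 0.05. Labels without any relation to the libraries are thus an unlikely source of either count. The test does not set zinc genes apart, since 90.2% of all tested genes changed.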
